A study of Mus musculus with 8 samples.

How the data were processed

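RNA-seq was done on liver of male C57BL/6N mice in 8 libraries. The mice received a normal chow diet with tap water or a western diet, which combined a high-fat diet with drinking water holding 23.1 g/L fructose and 18.9 g/L glucose. CCl4 or corn oil was injected into the peritoneum once a week, per the labels' protocols. The dose of CCl4, the duration of feeding and the age of the mice were not given in the sources used here. Libraries were prepared with the TruSeq Stranded mRNA kit, per the labels' protocols. By the labels, 3 libraries belonged to normal diet + oil, 2 to western diet + oil, 2 to normal diet + CCl4 and 1 to western diet + CCl4.

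The values were deposited as FPKM, fragments normalized to the length of the transcript and to the mapped fragments, for 55487 genes in each of the 8 libraries. FastQC 0.11.9, cutadapt 3.7, HISAT2 2.2.1, StringTie 2.1.0 and the genome build GRCm38 are named in the submitters' processing notes, and the step each tool performed is not given in the sources used here. Counts were not analysed here, so the depth of each library is unknown and no counting error was computed. The deposited FPKM summed to between 514832 and 612747 per library. In all, 38952 genes stood at 0 in every library, 11541 were above 0 in every library and 4994 in some. The lowest value above 0 lay between 0.252 and 0.318 FPKM in each library, so a value of 0 means unlisted or below such a level, not absent. For 27 genes the deposited symbol had been turned into a date by spreadsheet software, and these genes kept their identifiers. Coordinates came from GENCODE M21 on GRCm38, in which 55394 of the identifiers were found, 54559 of them with the same symbol. No pair of libraries shared an identical value among genes above 0 in both (0 in each of the pairs), so no library was a copy of another.

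Genes with an FPKM of at least 1 in at least 2 libraries were tested, which left 11514 genes. On log2(FPKM + 1) of these genes a linear model with a mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend). All libraries entered 1 fit, with 4 residual degrees of freedom, 3.93 prior degrees of freedom and 7.93 in total. The single western diet + CCl4 library was assumed to vary like the others. There were 7 contrasts: each of the 3 other groups against normal diet + oil, the 3 pairs among those groups, and the interaction of diet and CCl4. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within a contrast, and a gene was said to rise or fall at an adjusted p below 0.05. Nothing in the labels says whether libraries came from separate animals, so each p-value measures an effect against the spread between these libraries, which may be technical. Contrasts against normal diet + oil share the same 3 control libraries, and overlaps of their calls were therefore not computed.

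Before the data were examined, 35 gene lists with 627 distinct genes were written for cell types, pathways and liver zones. Lists with at least 5 tested members, 29 in number, were tested with limma's camera at the preset correlation between genes of 0.01, which compares a list with all other tested genes, and were adjusted over the lists within a contrast. The other 6 lists were not tested as lists. Members were also counted with p-values adjusted over the list alone. The genes named were fixed by a rule: in each contrast the up to 6 largest increases and 6 largest decreases among genes that passed and whose libraries did not overlap between the groups, without predicted genes and clones; the up to 4 members with the smallest p of each list that passed camera; and 14 fixed genes, 13 of which are given (Col1a1, Acta2, Timp1, Trem2, Cd68, Fasn, Scd1, Cidec, Cyp7a1, Cyp2e1, Afp, Mki67 and Cdkn1a). A gene named in 1 contrast could be given in others.

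The alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, rescaling to a common sum per library, median-of-ratios scaling, robust eBayes, the replicate number as a block, each library left out in turn, a fit of the compared groups alone, an additive model of diet and CCl4, and unadjusted p below 0.05 with a change of at least 2-fold. For lists, camera with an estimated correlation and fry were used as well. A further 3 alternatives were chosen after seeing the data: removal of the Mup family followed by rescaling, the same with each library left out in turn (for the first 2 contrasts), and a fit without normal diet + oil library 3 and normal diet + CCl4 library 1. The limma script was tested on simulated data with 200 changed genes per run. A change of 2 on the log2 scale was recovered for 97% of genes in the contrast of diets, 96% in that of CCl4 against oil, 89.5% in that of western diet + CCl4 against normal diet + oil and 62.5% in the interaction. For a change of 1 these shares were 46.5%, 54%, 2.5% and 0%. Genes called without a simulated change numbered 11, 18, 13 and 4 in the runs with a change of 2. These shares and counts test the script at the simulated spread. They do not give the power in these libraries, where counts of genes moved with single libraries. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.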

Results

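Liver RNA was compared between 4 groups of male C57BL/6N mice, with 3 libraries of normal diet + oil, 2 of western diet + oil, 2 of normal diet + CCl4 and 1 of western diet + CCl4. CCl4 is a liver toxin that cytochrome P450 enzymes, chiefly Cyp2e1, turn into a reactive radical. Values are FPKM, and depth is unknown because counts were not analysed here. Between 12531 and 14843 genes were above 0 in a library. The Mup family, the major urinary proteins made by hepatocytes, held 16.9%, 22.1% and 32.5% of the FPKM sum in normal diet + oil libraries 1, 2 and 3. Its share was 9.16% and 10.04% with western diet + oil, 2.80% and 4.65% with normal diet + CCl4, and 8.22% with western diet + CCl4. FPKM is a share of each library, so a fall in this family can raise the values of other genes. The median log2 fold change of all tested genes against normal diet + oil was 0.22 for the western diet, 0.26 for CCl4 and 0.19 for both. Under median-of-ratios scaling these medians became -0.000806, 0.00466 and 0.00647. That scaling centres the median ratio of each library, so medians near 0 follow from it and decide nothing about the cause.

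**Figure D1:**
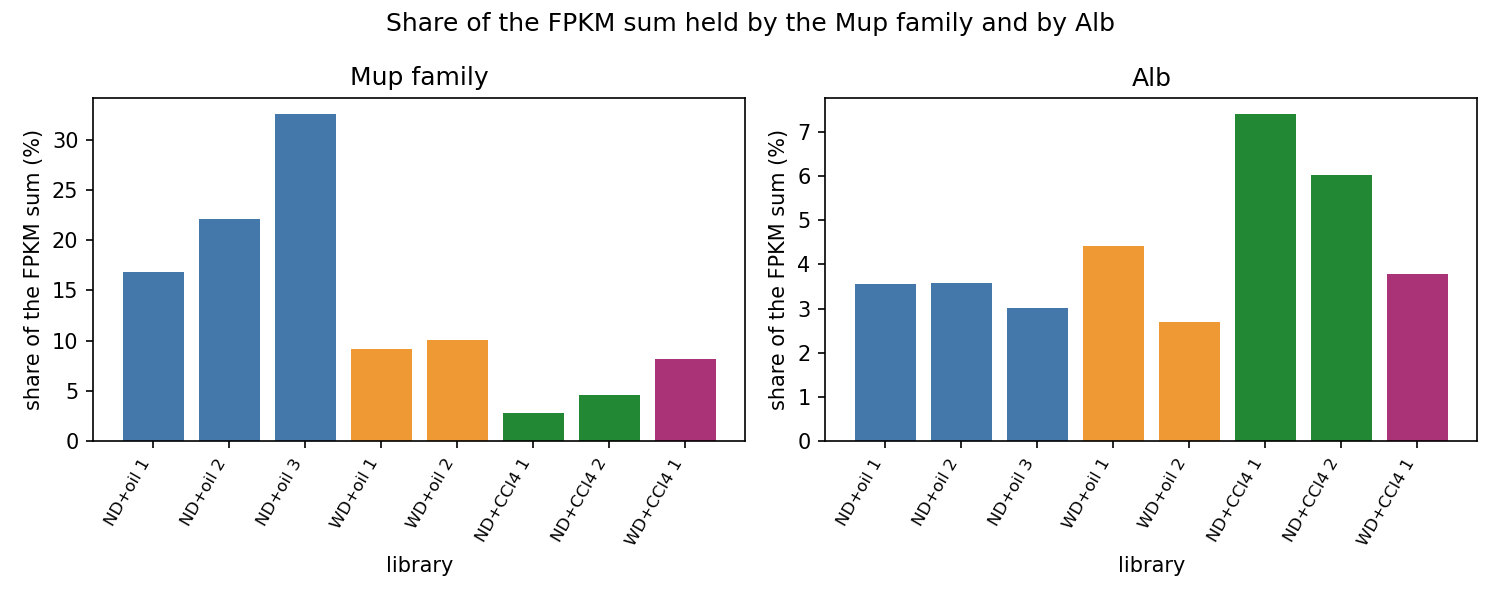
Share of the FPKM sum (%) held by the Mup family and by Alb in each of the 8 libraries, with 1 bar per library coloured by group. The Mup share lay between 16.9% and 32.5% with normal diet + oil and at 10.04% or less in every other library.

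The first comparison asked what the western diet did without CCl4. Cidea and Apoa4 were among the largest increases. Cidea, which enlarges lipid droplets (ENSMUSG00000024526, chromosome 18, 67343604 to 67367785 on GRCm38, protein coding), had 0.115 ± 0.199 FPKM (SD, n = 3) with normal diet + oil and 43.6 ± 12.4 (n = 2) with the western diet, a log2 fold change of 5.31 ± 0.22 (SE; limma adjusted p = 0.000129). Apoa4, an apolipoprotein of triglyceride-rich particles (ENSMUSG00000032080, chromosome 9, 46240696 to 46243459), went from 69.5 ± 11.8 to 2450 ± 433 FPKM, a log2 fold change of 5.12 ± 0.27 (limma adjusted p = 0.000351). Of 17 tested genes for lipid droplets and fatty acid uptake, 5 rose, 0 fell and 12 did not pass, and 12 rose when adjusted over the list alone. Their median log2 fold change was 1.04 (camera adjusted p = 8.41e-07; adjusted p = 0.461 with an estimated correlation). They included Cidec at 4.66 ± 0.40 (limma adjusted p = 0.00342), the fatty acid binding protein Fabp4 at 2.95 ± 0.32 (limma adjusted p = 0.0113) and the droplet coat protein Plin4 at 2.05 ± 0.27 (limma adjusted p = 0.0152). Fabp4 is also 1 of 3 tested adipose markers, a list too short for camera, of which 2 rose (median 2.95). When adjusted over the list alone, 2 of them rose and 1 fell. Among 28 genes of fatty acid oxidation and PPAR-alpha targets, 2 rose, 26 did not pass and 6 rose when adjusted over the list alone, with a median of 0.61 (camera adjusted p = 0.0028; adjusted p = 0.583 with an estimated correlation). The 2 were the omega-hydroxylases Cyp4a14 at 3.97 ± 0.59 and Cyp4a10 at 2.70 ± 0.57 (limma adjusted p = 0.0193 and 0.0427). Of 23 genes of lipogenesis 2 rose and 21 did not pass, while 8 rose and 1 fell when adjusted over the list alone. Their median was 0.65, and the list did not pass (camera adjusted p = 0.0897; adjusted p = 0.756 with an estimated correlation). It passed camera with median-of-ratios scaling (adjusted p = 0.0278) and without the Mup family (0.017). Neither Fasn, at 0.80 ± 0.44 (limma adjusted p = 0.325), nor Scd1, at 1.64 ± 0.56 (0.136), passed.

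Cholesterol synthesis fell. Of 25 tested SREBP2 targets and enzymes of the pathway, 0 rose, 10 fell and 15 did not pass, while 16 fell and 1 rose when adjusted over the list alone. The median log2 fold change was -0.92 (camera adjusted p = 8.81e-29; adjusted p = 0.262 with an estimated correlation). Idi1, the isomerase of isopentenyl diphosphate (ENSMUSG00000058258, chromosome 13, 8885501 to 8892451), went from 33.9 ± 4.54 to 4.82 ± 2.28 FPKM, and Sqle, the squalene epoxidase, from 23.5 ± 3.94 to 2.98 ± 2.69. Their log2 fold changes were -2.64 ± 0.33 and -2.79 ± 0.39 (limma adjusted p = 0.0142 and 0.0183). Nsdhl, at -1.88 ± 0.23, and Cyp51, at -1.95 ± 0.28, also fell (limma adjusted p = 0.0142 and 0.0193). Male-biased liver genes also lay lower as a list, with 6 of 16 lower, 0 higher and 10 not passing, and 11 lower when adjusted over the list alone. Their median was -1.27 (camera adjusted p = 6.49e-21; adjusted p = 0.236 with an estimated correlation). Hsd3b5, a male-specific steroid dehydrogenase, went from 106 ± 29.5 to 5.43 ± 5.12 FPKM (-4.30 ± 0.49, limma adjusted p = 0.0125). Serpina1e, at -2.92 ± 0.28, Mup12, at -3.24 ± 0.43, and Mup7, at -3.15 ± 0.43, were among the largest decreases (limma adjusted p = 0.00713, 0.0152 and 0.0171). The 42 tested Mup genes, of which 41 lie on chromosome 4, are near-identical copies whose fragments cannot be assigned with certainty, and 37 of them had a log2 fold change below 0.

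Markers of macrophages were among the genes that rose with the western diet. Of 15 tested Kupffer cell and macrophage markers, 12 rose, 0 fell and 3 did not pass, and 14 rose when adjusted over the list alone, with a median log2 fold change of 2.36 (camera adjusted p = 1.8e-10; adjusted p = 0.461 with an estimated correlation). Marco, a scavenger receptor (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024), went from 3.36 ± 2.03 to 52.5 ± 24.7 FPKM (3.65 ± 0.44, limma adjusted p = 0.0139), and Cd5l from 17.7 ± 6.22 to 164 ± 73.3 (3.13 ± 0.50, limma adjusted p = 0.0235). Timd4, a marker of resident Kupffer cells, rose by 1.77 ± 0.27 on the log2 scale (limma adjusted p = 0.0201). Of 14 markers of monocyte-derived and lipid-associated macrophages, 3 rose and 11 did not pass, while 10 rose and 1 fell when adjusted over the list alone. Their median was 1.74 (camera adjusted p = 0.00164; adjusted p = 0.583 with an estimated correlation). Lpl went from 2.51 ± 0.894 to 23.1 ± 2.44 FPKM (2.81 ± 0.46, limma adjusted p = 0.0246). Trem2 was listed at 0 in all 3 normal diet + oil libraries and at 3.14 and 9.27 FPKM with the western diet, and did not pass (limma adjusted p = 0.113), nor did Cd68 (2.60 ± 0.66, limma adjusted p = 0.0676). Chemokine and inflammation genes had 7 of 16 higher, 9 not passing and 12 higher when adjusted over the list alone. Their median was 1.22 (camera adjusted p = 4.14e-05; adjusted p = 0.503 with an estimated correlation), with Ccl2, which recruits monocytes, at 0.172 ± 0.298 and 3.81 ± 0.214 FPKM (2.07 ± 0.28, limma adjusted p = 0.0152). Haemoglobin genes, a sign of blood in the tissue, moved in the same libraries: Hba-a1 was 70.2 ± 12.7 and 194 ± 62.7 FPKM (1.43 ± 0.26, limma adjusted p = 0.0284). Of the 5 erythroid genes, 3 rose, 2 did not pass and 4 rose when adjusted over the list alone. Their median was 1.43 (camera adjusted p = 0.0239; adjusted p = 0.543 with an estimated correlation), a list call that ended without western diet + oil library 1 (0.0858), normal diet + CCl4 library 1 (0.127) or library 2 (0.139).

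Markers of other sinusoidal cells were higher as well. Of 16 stellate cell and myofibroblast markers, 3 rose, 13 did not pass and 9 rose when adjusted over the list alone. Their median was 0.94 (camera adjusted p = 0.000141; adjusted p = 0.543 with an estimated correlation), with Colec11, a collectin, at 7.75 ± 0.597 and 26.0 ± 4.46 FPKM (1.62 ± 0.22, limma adjusted p = 0.0152). Of 24 genes of the extracellular matrix, 4 rose, 20 did not pass and 12 rose when adjusted over the list alone. Their median was 1.06 (camera adjusted p = 0.000329; adjusted p = 0.583 with an estimated correlation). Decorin (Dcn) went from 25.6 ± 2.12 to 74.9 ± 3.55 FPKM (1.51 ± 0.30, limma adjusted p = 0.0365) and Postn rose by 2.01 ± 0.36 on the log2 scale (limma adjusted p = 0.0275). Col1a1, the main fibrillar collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), stood at 1.12 ± 1.35 and 3.24 ± 1.16 FPKM and did not pass (1.15 ± 0.74, limma adjusted p = 0.395), nor did Acta2 (0.32 ± 0.42, 0.679) or Timp1 (0.90 ± 0.68, 0.459). The 14 sinusoidal endothelial markers had 3 higher, 11 not passing and 10 higher when adjusted over the list alone. Their median was 0.89 (camera adjusted p = 4.14e-05; adjusted p = 0.503 with an estimated correlation), Stab2 among them at 1.06 ± 0.20 (limma adjusted p = 0.0325).

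Among genes of hepatocytes, xenobiotic P450 enzymes and bile acid genes moved both ways with the western diet. Of 25 P450 genes, 2 rose, 2 fell and 21 did not pass, while 3 rose and 7 fell when adjusted over the list alone. Their median was -0.09 (camera direction down, adjusted p = 8.98e-07; adjusted p = 0.461 with an estimated correlation). Cyp1a2 (ENSMUSG00000032310, chromosome 9, 57676937 to 57683703) went from 244 ± 40.9 to 48.6 ± 2.67 FPKM (-2.29 ± 0.25, limma adjusted p = 0.0111), and the inducible Cyp2b9 rose by 2.22 ± 0.44 on the log2 scale (limma adjusted p = 0.0369). Cyp2e1, which activates CCl4, was 2160 ± 329 and 2020 ± 193 FPKM (-0.09 ± 0.23, limma adjusted p = 0.843). In bile acid metabolism 1 gene rose, 2 fell and 17 of 20 did not pass, while 3 rose and 2 fell when adjusted over the list alone. Their median was -0.05 (camera direction down, adjusted p = 0.00164; adjusted p = 0.461 with an estimated correlation). Cyp7b1, an oxysterol hydroxylase, went from 125 ± 42.8 to 22.6 ± 0.169 FPKM (-2.36 ± 0.28, limma adjusted p = 0.0137), the uptake transporter Slco1a1 changed by -1.69 ± 0.23 (limma adjusted p = 0.0152) and the phospholipid exporter Abcb4 by 0.78 ± 0.16 (limma adjusted p = 0.0433). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass (0.42 ± 0.24, limma adjusted p = 0.339). Of 10 oncofetal and liver tumour genes 1 rose, 9 did not pass and 2 rose when adjusted over the list alone. Their median was 0.97 (camera adjusted p = 0.0298; adjusted p = 0.63 with an estimated correlation), a call that ended without normal diet + oil library 1 (0.083) or western diet + oil library 1 (0.0675). That gene was Ly6d, a lipid-anchored surface protein (ENSMUSG00000034634, chromosome 15, 74762056 to 74763620), which went from 0.782 ± 0.419 to 68.8 ± 6.42 FPKM (5.31 ± 0.57, limma adjusted p = 0.0105). Complement factor D (Cfd), an adipokine, went from 0.270 ± 0.468 to 21 ± 3.15 FPKM (4.17 ± 0.28, limma adjusted p = 0.00127). The 13 mitochondrially encoded genes lay lower than other genes, with 0 passing (median -0.15, camera adjusted p = 0.00164; adjusted p = 0.503 with an estimated correlation), a call that ended without western diet + oil library 2 (0.102).

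Of 11514 tested genes, 508 passed in the comparison of diets, 439 of them higher and 69 lower (86.4% higher), and with median-of-ratios scaling 285 passed, 214 higher and 71 lower (75.1%). The count rested on single libraries. It was 75, 69 and 119 without normal diet + oil libraries 1, 2 and 3, 8 and 4 without western diet + oil libraries 1 and 2, and 1099 and 1159 without normal diet + CCl4 libraries 1 and 2. Cidea and Apoa4 were the 2 of 56 named genes that were tested and passed limma without each library in turn, and 36 of the 56 passed with median-of-ratios scaling. No list in any comparison passed camera with an estimated correlation.

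**Figure D2:**
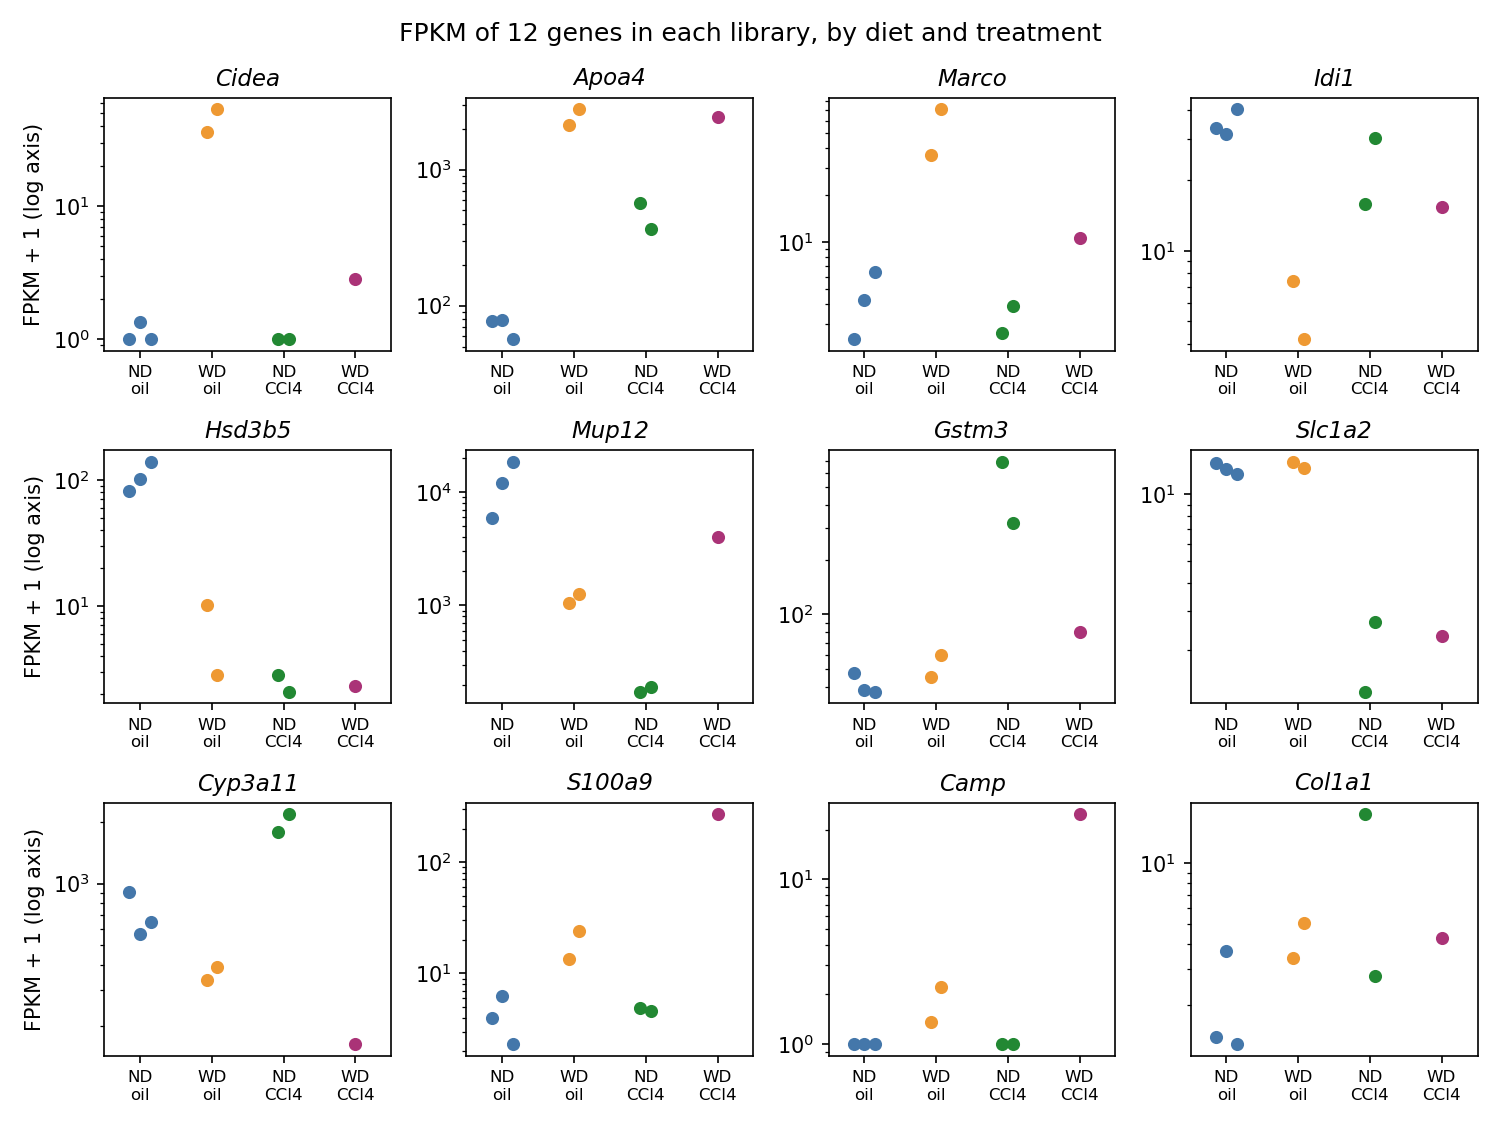
FPKM + 1 on a log axis of 12 genes, with 1 point per library and the 4 groups side by side (ND, normal diet; WD, western diet). Cidea and Marco were highest in both western diet + oil libraries, Mup12 was lowest in both normal diet + CCl4 libraries, and S100a9 and Camp were highest in the western diet + CCl4 library.

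The second comparison asked what CCl4 did with the normal diet. Genes of glutathione conjugation were among those that rose and male-biased genes among those that fell. Gstm3, a glutathione transferase (ENSMUSG00000004038, chromosome 3, 107963696 to 107969283), went from 40.3 ± 5.58 FPKM (SD, n = 3) to 501 ± 263 (n = 2), a log2 fold change of 3.51 ± 0.33 (SE; limma adjusted p = 0.0044). Gsta2 went from 9.78 ± 3.14 to 92.8 ± 3.16 FPKM (3.16 ± 0.31, limma adjusted p = 0.00518), and Nqo1, a quinone reductase under NRF2, from 2.30 ± 0.537 to 8.63 ± 4.08 (1.49 ± 0.27, limma adjusted p = 0.0435). Of 21 NRF2 and glutathione genes, 4 rose, 0 fell and 17 did not pass, 11 rose when adjusted over the list alone, and all 21 had a log2 fold change above 0 (median 0.92, camera adjusted p = 2.67e-05; adjusted p = 0.7 with an estimated correlation). Of 28 genes of fatty acid oxidation and PPAR-alpha targets, 4 rose and 24 did not pass, while 16 rose and 1 fell when adjusted over the list alone. Their median was 0.60 (camera adjusted p = 0.00232; adjusted p = 0.706 with an estimated correlation). Cyp4a14 rose by 3.84 ± 0.59 and Cyp4a10 by 3.09 ± 0.57 on the log2 scale (limma adjusted p = 0.0286 and 0.046). Ly6d was 79.0 ± 74.9 FPKM after CCl4 (5.10 ± 0.57, limma adjusted p = 0.0087). Of 25 xenobiotic P450 genes 5 rose, 1 fell and 19 did not pass, while 9 rose and 5 fell when adjusted over the list alone. Their median was 0.37, and the list did not pass (camera adjusted p = 0.183). Of 9 female-biased genes 3 rose and of 14 periportal markers 2 rose, and neither list passed (camera adjusted p = 0.34 and 0.0671).

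Of 16 male-biased genes, 7 fell, 0 rose and 9 did not pass, 12 fell when adjusted over the list alone, and all 16 were below 0 (median -1.43, camera adjusted p = 1.31e-34; adjusted p = 0.0916 with an estimated correlation). Hsd3b5 reached 1.44 ± 0.52 FPKM (-5.44 ± 0.49, limma adjusted p = 0.00425), and Slco1a1 (ENSMUSG00000041698, chromosome 6, 141907282 to 141946962) went from 59.2 ± 8.91 to 4.93 ± 1.01 (-3.34 ± 0.23, limma adjusted p = 0.00205). Mup12 (ENSMUSG00000094793, chromosome 4, 60737383 to 60741326) went from 12000 ± 6280 to 182 ± 12.4 FPKM (-5.89 ± 0.43, limma adjusted p = 0.00205) and Mup15 from 10500 ± 2440 to 324 ± 26.5 (-5.0 ± 0.29, limma adjusted p = 0.00148). Of the 42 Mup genes, 41 were below 0 and 19 fell, with the same doubt over the assignment of fragments. Markers of pericentral hepatocytes, the cells around the central vein where Cyp2e1 is made, fell in part: 2 of 13 fell, 11 did not pass and 6 fell when adjusted over the list alone. Their median was -0.12 (camera adjusted p = 2.55e-10; adjusted p = 0.134 with an estimated correlation). Glutamine synthetase (Glul; ENSMUSG00000026473, chromosome 1, 153899944 to 153909723) went from 199 ± 23.6 to 57.6 ± 20.8 FPKM (-1.81 ± 0.25, limma adjusted p = 0.0227), and the glutamate transporter Slc1a2 from 12.1 ± 0.739 to 0.985 ± 0.967 (-2.81 ± 0.28, limma adjusted p = 0.00518). Cyp2e1 was 2300, 2410 and 1790 FPKM with oil against 1070 and 1350 with CCl4 and did not pass (-0.84 ± 0.23, limma adjusted p = 0.116). In bile acid metabolism 2 of 20 genes fell, 18 did not pass, and 4 rose and 3 fell when adjusted over the list alone. Their median was -0.19 (camera adjusted p = 9.51e-07; adjusted p = 0.246 with an estimated correlation), with Cyp7b1 at -2.36 ± 0.28 (limma adjusted p = 0.0123). Of 25 cholesterol genes 0 passed over all genes, and 9 fell and 1 rose when adjusted over the list alone. Their median was -0.66 (camera adjusted p = 1.74e-23; adjusted p = 0.246 with an estimated correlation).

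Proliferation, matrix and tumour-associated genes were higher after CCl4 as lists, with values that differed between the 2 CCl4 libraries. Of 20 cell cycle genes, 1 rose, 19 did not pass, 15 rose when adjusted over the list alone and all 20 were above 0 (median 1.32, camera adjusted p = 2.15e-05; adjusted p = 0.706 with an estimated correlation). Cyclin D1 (Ccnd1) went from 2.44 ± 0.818 to 20.1 ± 13.7 FPKM (2.47 ± 0.40, limma adjusted p = 0.034). Mki67, a marker of dividing cells, was listed at 0 in all normal diet + oil libraries, at 7.40 FPKM in CCl4 library 1 and at 0 in library 2. Of 24 matrix genes, 0 passed over all genes and 14 rose when adjusted over the list alone. Their median was 1.03 (camera adjusted p = 0.00148; adjusted p = 0.706 with an estimated correlation), a call that ended without CCl4 library 1 (0.0896). Col1a1 was 16.4 and 1.77 FPKM in the 2 CCl4 libraries (1.89 ± 0.74, limma adjusted p = 0.193), Acta2 4.27 and 0.83 (0.74 ± 0.42, 0.303), Timp1 3.07 and 0.49 (0.65 ± 0.68, 0.539), Trem2 9.82 and 0, and Cd68 29.5 and 4.60 (1.5 ± 0.66, 0.226). Of 16 stellate cell markers, 1 rose, 15 did not pass and 5 rose when adjusted over the list alone. Their median was 0.77 (camera adjusted p = 0.0231; adjusted p = 0.706 with an estimated correlation), with 0.721 without CCl4 library 1. Rgs5, a pericyte marker, rose by 1.30 ± 0.24 on the log2 scale (limma adjusted p = 0.046). Of 10 oncofetal and liver tumour genes, 1 rose, 9 did not pass and 7 rose when adjusted over the list alone. Their median was 1.5 (camera adjusted p = 0.0162; adjusted p = 0.706 with an estimated correlation), with 0.402 without CCl4 library 1 and 0.134 without the western diet + CCl4 library. Afp, the fetal albumin, was too low for the test, at 14.7 FPKM in CCl4 library 1, 0.741 in library 2 and at most 0.571 with oil. The acute phase list lay lower than other genes, with 0 of 26 passing (median -0.24, camera adjusted p = 7.98e-07; adjusted p = 0.578 with an estimated correlation), and its member Saa1 was 1050 ± 901 FPKM with oil and 56.0 ± 13.8 after CCl4 (-3.52 ± 1.04, limma adjusted p = 0.131).

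Further lists passed camera after CCl4, and none did with an estimated correlation. All 14 sinusoidal endothelial markers were above 0, with 0 passing over all genes and 10 higher when adjusted over the list alone (median 0.75, camera adjusted p = 0.000932; adjusted p = 0.706 with an estimated correlation). Lower than other genes, with 0 passing, lay lipogenesis (median -0.23, camera adjusted p = 1.32e-07), the mitochondrially encoded genes (-0.1, 0.000205) and the erythroid genes (-0.11, 0.0232). The lipogenesis call ended without CCl4 library 1 (0.179), and the erythroid call without normal diet + oil library 3 (0.231) or CCl4 library 1 (0.494).

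For CCl4, 164 genes passed, 118 higher and 46 lower (72.0% higher). The split turned with the scaling, to 44 higher and 56 lower (44.0%) of 100 with median-of-ratios factors and to 301 higher and 56 lower (84.3%) of 357 when each library was rescaled to a common sum. It was 44.4% with no filter, 30.6% with the replicate block, and 31.8% and 90.9% without CCl4 libraries 1 and 2. The count was 60, 42 and 76 without normal diet + oil libraries 1, 2 and 3, 47 and 56 without western diet + oil libraries 1 and 2, and 22 and 1165 without normal diet + CCl4 libraries 1 and 2. Without each library in turn, 9 of 23 named genes still passed limma, namely Ly6d, Gstm3, Mup12, Mup13, Mup15, Mup17, Hsd3b5, Slco1a1 and Slc1a2, and 15 of the 23 passed with median-of-ratios scaling.

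**Figure D3:**
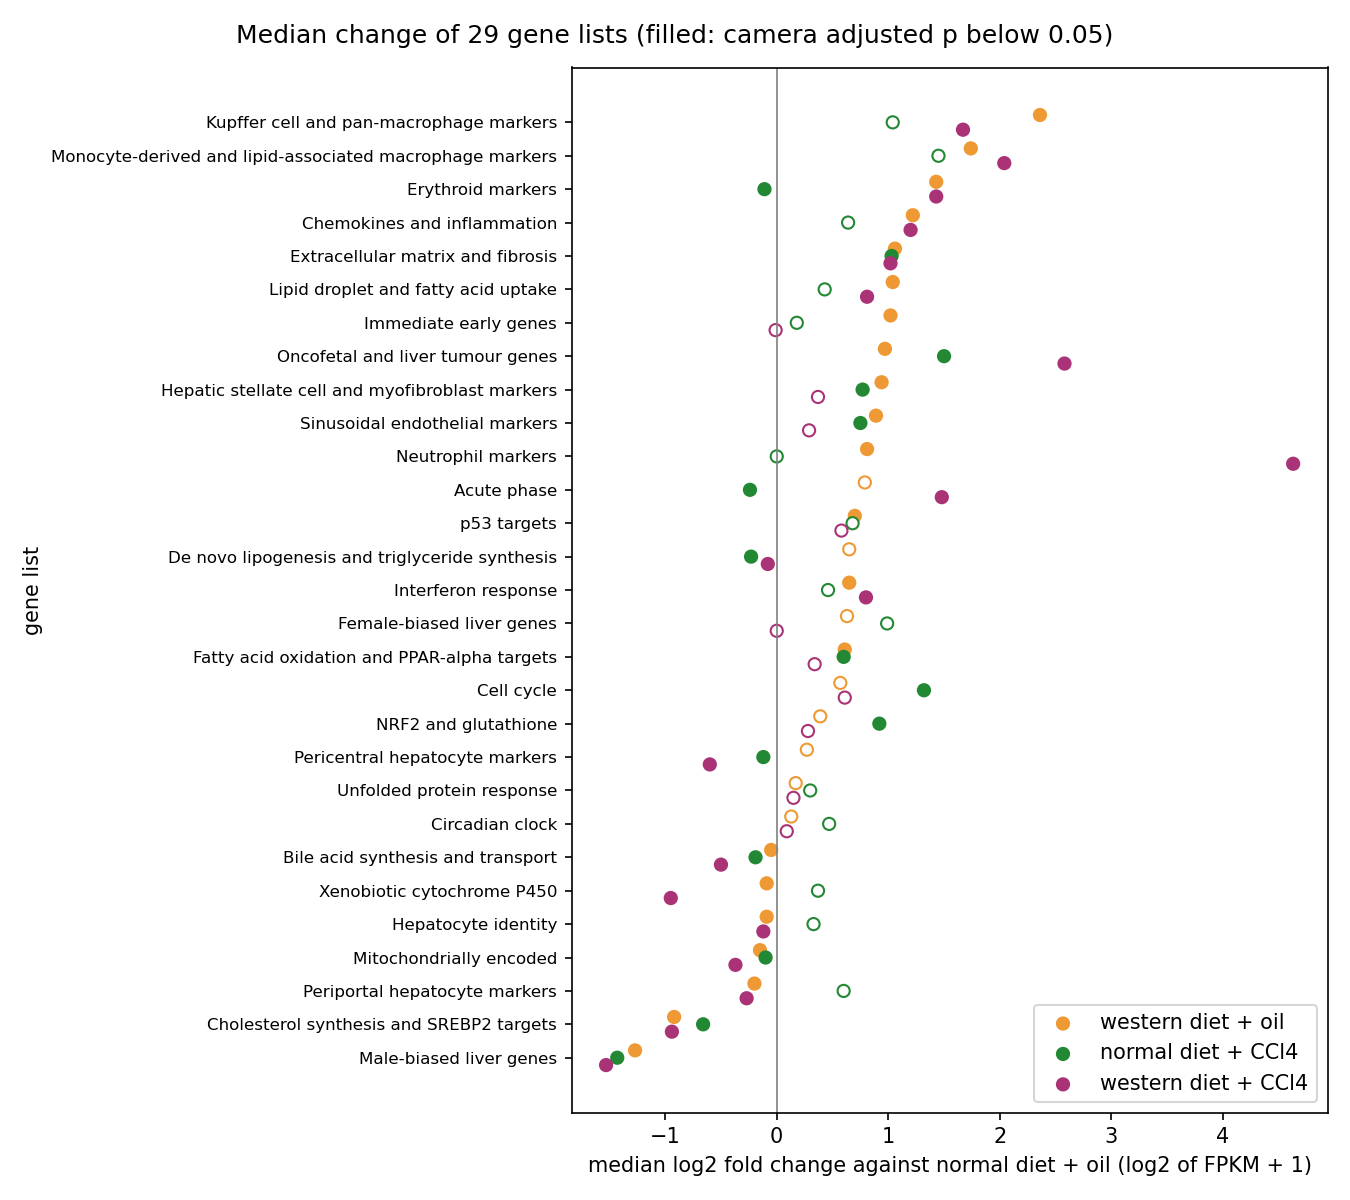
Median log2 fold change against normal diet + oil, on log2(FPKM + 1), of 29 gene lists in the 3 other groups, with filled points for camera adjusted p below 0.05 at the preset correlation. The neutrophil markers reached a median of 4.63 with western diet + CCl4, and the male-biased genes lay between -1.53 and -1.27 in the 3 groups.

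The third comparison set western diet + CCl4 against normal diet + oil and rested on 1 library against 3. Genes of neutrophils were among the largest increases. S100a9, a subunit of calprotectin (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721), was 267 FPKM against 3.19 ± 1.99 (SD, n = 3), a log2 fold change of 6.12 ± 0.51 (SE; limma adjusted p = 0.00364). The cathelicidin gene Camp (ENSMUSG00000038357, chromosome 9, 109847379 to 109849617) was 23.8 FPKM (4.63 ± 0.29, limma adjusted p = 0.00218) and Ngp 36.7 FPKM, against 0 in every normal diet + oil library (5.24 ± 0.43, limma adjusted p = 0.00364). Of 7 neutrophil markers 6 rose, 1 did not pass, and 7 rose when adjusted over the list alone. Their median was 4.63 (camera adjusted p = 9.29e-16; adjusted p = 0.193 with an estimated correlation). Of 26 acute phase genes, 1 rose and 25 did not pass, while 21 rose and 1 fell when adjusted over the list alone. Their median was 1.48 (camera adjusted p = 4.01e-09; adjusted p = 0.28 with an estimated correlation). The gene that rose was Serpina3n, an inhibitor of serine proteases, at 131 ± 31.6 and 665 FPKM (2.36 ± 0.34, limma adjusted p = 0.0287). The erythroid genes lay higher in the same library, with 0 of 5 passing and 4 higher when adjusted over the list alone. Their median was 1.43 (camera adjusted p = 0.00341; adjusted p = 0.414 with an estimated correlation). Of 10 oncofetal and tumour genes 3 rose, 7 did not pass and 8 rose when adjusted over the list alone. Their median was 2.58 (camera adjusted p = 1.88e-07; adjusted p = 0.357 with an estimated correlation): Ly6d at 6.98 ± 0.72, Spink1 at 3.98 ± 0.56 and Tff3 at 4.62 ± 0.70 (limma adjusted p = 0.00696, 0.0265 and 0.0335). Of 14 monocyte-derived macrophage markers 2 rose, 12 did not pass and 7 rose when adjusted over the list alone. Their median was 2.04 (camera adjusted p = 2e-05; adjusted p = 0.465 with an estimated correlation), with Cd63 at 4.64 ± 0.72 (limma adjusted p = 0.0355).

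Some drug-metabolizing P450 genes fell in this library. Of 25, 6 fell, 0 rose and 19 did not pass, and 10 fell and 2 rose when adjusted over the list alone. Their median was -0.95 (camera adjusted p = 1.42e-12; adjusted p = 0.216 with an estimated correlation). Cyp2c29 went from 507 ± 20.8 to 26.3 FPKM (-4.22 ± 0.54, limma adjusted p = 0.0185), Cyp2c37 from 99.7 ± 16.3 to 6.05 (-3.82 ± 0.49, limma adjusted p = 0.0188) and Cyp3a11 (ENSMUSG00000056035, chromosome 5, 145854426 to 145879964) from 709 ± 182 to 163 (-2.08 ± 0.32, limma adjusted p = 0.0335). Cyp2e1 was 1030 FPKM and did not pass (-1.06 ± 0.29, limma adjusted p = 0.147). Of 16 male-biased genes, 4 fell, 12 did not pass and 10 fell when adjusted over the list alone. Their median was -1.53 (camera adjusted p = 3.1e-18; adjusted p = 0.193 with an estimated correlation), Hsd3b5 among them at -5.49 ± 0.62 (limma adjusted p = 0.00914). Of 20 bile acid genes 2 fell, 18 did not pass and 3 fell when adjusted over the list alone. Their median was -0.50 (camera adjusted p = 4.01e-09; adjusted p = 0.193 with an estimated correlation). The pericentral list had 2 of 13 lower and 11 not passing, with 2 higher and 5 lower when adjusted over the list alone. Their median was -0.60 (camera adjusted p = 3.41e-05; adjusted p = 0.216 with an estimated correlation), with Slc1a2 at -2.49 ± 0.35 (limma adjusted p = 0.0265). No cholesterol gene passed over all genes, 0 of 25, and 15 fell and 1 rose when adjusted over the list alone. Their median was -0.94 (camera adjusted p = 1.29e-18; adjusted p = 0.216 with an estimated correlation).

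The lipid droplet and matrix lists were higher in this library. Of 17 lipid droplet genes 2 rose, 15 did not pass and 6 rose when adjusted over the list alone. Their median was 0.81 (camera adjusted p = 0.0021; adjusted p = 0.521 with an estimated correlation), with Fabp4 at 2.92 ± 0.41 and Cidec at 2.91 ± 0.51 (limma adjusted p = 0.0265 and 0.0488). Apoa4 was 2420 FPKM (5.12 ± 0.34, limma adjusted p = 0.00218). Of 24 matrix genes 0 passed, also when adjusted over the list alone, although all 24 were above 0 (median 1.02, camera adjusted p = 0.000825; adjusted p = 0.658 with an estimated correlation), and Col1a1 was 3.30 FPKM (1.20 ± 0.94, limma adjusted p = 0.591). Other lists also passed camera, at the preset correlation alone. Kupffer markers (median 1.67, camera adjusted p = 0.00072), chemokine and inflammation genes (1.2, 2e-05) and interferon response genes (0.8, 0.00098) were higher. The mitochondrially encoded genes lay lower, with 12 of 13 below 0 (median -0.37, camera adjusted p = 4.94e-06; adjusted p = 0.312 with an estimated correlation). Hepatocyte identity genes (-0.12, 0.00223), periportal markers (-0.27, 0.0181) and lipogenesis (-0.08, 0.0128) lay lower as well. The lipogenesis call ended without normal diet + oil library 1 (0.122) or 2 (0.0562), and with median-of-ratios scaling (0.057), as did the periportal call (0.0723).

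In this comparison 107 genes passed, 77 higher and 30 lower (72.0% higher). The split was 24 against 19 (55.8%) with a pseudocount of 0.1, and 21 against 21 (50%) with a mean FPKM of at least 5. With no filter it was 160 against 11 (93.6%). The count was 36, 49 and 53 without normal diet + oil libraries 1, 2 and 3, 38 and 36 without western diet + oil libraries 1 and 2, and 442 and 486 without normal diet + CCl4 libraries 1 and 2. Of 27 named genes, 8 still passed limma without each library in turn: Ly6d, S100a8, S100a9, Apoa4, Ubd, Hsd3b5, Cyp1a2 and Slco1a1. Ngp, Camp and Ltf passed where tested, but were below the filter without western diet + oil library 2.

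The effect of CCl4 on top of the western diet was compared between 1 and 2 libraries, and 5 genes passed. Camp, Ltf and Retnlg, genes of neutrophil granules, were higher, at log2 fold changes of 3.82 ± 0.31, 3.02 ± 0.30 and 3.00 ± 0.32 (SE; limma adjusted p = 0.00956, 0.027 and 0.0335). Cfd went from 21 ± 3.15 FPKM (SD, n = 2) to 0 (-4.45 ± 0.37, limma adjusted p = 0.00956) and Cidea from 43.6 ± 12.4 to 1.81 (-3.96 ± 0.30, limma adjusted p = 0.00956). All 3 adipose markers, Cfd among them, were below 0 (median -2.2), and 1 fell over all genes and 2 when adjusted over the list alone. Of 7 neutrophil markers 3 rose, 4 did not pass and 7 rose when adjusted over the list alone. Their median was 3.69 (camera adjusted p = 1.03e-28; adjusted p = 0.184 with an estimated correlation). Of 26 acute phase genes 0 passed and 5 rose when adjusted over the list alone. Their median was 0.95 (camera adjusted p = 8.66e-14; adjusted p = 0.329 with an estimated correlation). All 23 lipogenesis genes were below 0, with 0 passing (median -0.64, camera adjusted p = 1.99e-08; adjusted p = 0.472 with an estimated correlation), and Fasn was 87.8 ± 0.657 and 23.7 FPKM (-1.84 ± 0.59, limma adjusted p = 0.876). Of 15 Kupffer markers 0 passed and 3 fell when adjusted over the list alone. Their median was -0.75 (camera adjusted p = 7.23e-07; adjusted p = 0.472 with an estimated correlation). Markers of other sinusoidal cells were lower too, with 0 passing: all 14 endothelial markers were below 0 (median -0.59, camera adjusted p = 2.43e-09; adjusted p = 0.472 with an estimated correlation), and 13 of 16 stellate markers (-0.42, 0.00607; 0.774), a call that ended without western diet + oil library 2 (0.241). Further lists passed camera at the preset correlation alone. Pericentral markers (median -0.7, camera adjusted p = 1.15e-05), P450 genes (-0.52, 4.74e-06), bile acid genes (-0.37, 5.44e-05), lipid droplet genes (-0.2, 0.000698) and immediate early genes (-0.96, 1.15e-05) were lower. Oncofetal genes were higher (1.26, 8.64e-09). Mitochondrially encoded genes were lower (-0.27, 0.0261), which ended without western diet + oil library 1 (0.632), either normal diet + CCl4 library (0.0559) and with median-of-ratios scaling (0.068). Cholesterol genes were higher (0.17, 0.00789), which ended without western diet + oil library 2 (0.509). Monocyte-derived macrophage markers were higher (0.18, 0.0261), which ended without western diet + oil library 1 (0.263), normal diet + CCl4 library 1 (0.235) and with median-of-ratios scaling (0.0531). The count of 5 became 3 without any normal diet + oil library, 3 and 1 without western diet + oil libraries 1 and 2, and 13 and 16 without normal diet + CCl4 libraries 1 and 2. Rescaled to a common sum, 2 were higher and 3 lower (40% against 60% higher), without the Mup family 2 were higher and 2 lower, and with no filter 65 were higher and 4 lower (94.2%). Of the 5 genes, 0 passed limma with a pseudocount of 0.1 (416 genes at an unadjusted p below 0.05) or with the replicate number as a block (436). None was tested and called without each library in turn: Camp and Cfd passed where tested, but were below the filter without western diet + oil library 2, and Cfd also without library 1.

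Between western diet + CCl4 and normal diet + CCl4, the effect of diet under CCl4, 30 genes passed, 19 higher and 11 lower. Neutrophil genes were again among the increases: S100a9 at 5.81 ± 0.54 and Camp at 4.63 ± 0.31 (SE; limma adjusted p = 0.00835 and 0.00508). Of the 7 neutrophil markers 6 rose, 1 did not pass and 7 rose when adjusted over the list alone. Their median was 4.63 (camera adjusted p = 1.63e-27; adjusted p = 0.169 with an estimated correlation). Ighg1, an immunoglobulin heavy chain, was 18 FPKM against 0 in both normal diet + CCl4 libraries (4.25 ± 0.41, limma adjusted p = 0.00835). Of 26 acute phase genes 0 passed, and 17 rose and 1 fell when adjusted over the list alone. Their median was 1.68 (camera adjusted p = 9.96e-25; adjusted p = 0.169 with an estimated correlation). The erythroid genes lay higher beside them, with 0 of 5 passing and 4 higher when adjusted over the list alone. Their median was 1.54 (camera adjusted p = 1.52e-06; adjusted p = 0.279 with an estimated correlation). Of 25 P450 genes 3 fell, 22 did not pass and 8 fell when adjusted over the list alone. Their median was -1.15 (camera adjusted p = 9.08e-12; adjusted p = 0.279 with an estimated correlation). Cyp3a11 went from 1990 ± 273 FPKM (SD, n = 2) to 163 (-3.59 ± 0.34, limma adjusted p = 0.00835) and Cyp2c55 from 12.1 ± 2.09 to 0 (-3.70 ± 0.36, limma adjusted p = 0.00896). The mean of Cyp3a11 with normal diet + CCl4 lay above that with normal diet + oil. Of 21 NRF2 and glutathione genes 0 passed and 8 fell when adjusted over the list alone. Their median was -0.81 (camera adjusted p = 2.81e-07; adjusted p = 0.58 with an estimated correlation). The cell cycle list, 0 of 20 passing, lay lower (median -0.87, camera adjusted p = 0.000328; adjusted p = 0.653 with an estimated correlation) but not without normal diet + CCl4 library 1 (0.479). Further lists passed camera at the preset correlation alone. Kupffer markers (median 0.77, camera adjusted p = 2.17e-05), lipid droplet genes (0.52, 0.000328) and chemokine genes (0.53, 1.88e-05) were higher, and periportal markers lower (-0.92, 3.88e-06). Endothelial markers were lower (-0.51, 0.000328), but not without normal diet + CCl4 library 1 (0.0604). Calls that ended without normal diet + CCl4 library 2 were monocyte-derived macrophage markers (0.63, 0.000112; 0.739 without it), oncofetal genes (0.96, 1.88e-05; 0.38) and interferon response genes (0.22, 0.0122; 0.752), all higher, and hepatocyte identity genes (-0.25, 0.0248; 0.903), lower. The split turned to 4 higher and 11 lower (26.7%) with a pseudocount of 0.1 and to 13 and 19 (40.6%) without normal diet + CCl4 library 2, and was 99 and 10 (90.8%) with no filter. The count of 30 was 14 without normal diet + oil library 2 and 17 and 6 without western diet + oil libraries 1 and 2. S100a9 passed limma without each library in turn, and Ighg1, Camp, Ngp, Ltf and Retnlg in 6 of 7 such fits, being below the filter in the other.

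The diet and the toxin were also compared directly, with 2 western diet + oil against 2 normal diet + CCl4 libraries, and 71 genes passed, 47 higher and 24 lower with the diet. Cidea at 5.45 ± 0.24, Cidec at 4.08 ± 0.44 and Fitm1, an organizer of lipid droplets, at 3.85 ± 0.56 were higher with the diet (SE; limma adjusted p = 0.000214, 0.0163 and 0.0317). Of 17 lipid droplet genes 4 rose, 13 did not pass, and 7 rose and 1 fell when adjusted over the list alone. Their median was 0.66 (camera adjusted p = 1e-06; adjusted p = 0.461 with an estimated correlation). Of 3 adipose markers 1 rose, and 2 rose when adjusted over the list alone (median 1.58). Of 15 Kupffer and macrophage markers 3 rose, 12 did not pass and 12 rose when adjusted over the list alone. Their median was 1.57 (camera adjusted p = 1.26e-13; adjusted p = 0.371 with an estimated correlation), with Marco at 52.5 ± 24.7 against 2.26 ± 0.888 FPKM (SD, n = 2 each; 3.98 ± 0.48, limma adjusted p = 0.0191). The erythroid genes were higher with the diet in the same libraries, with 0 of 5 passing and 4 higher when adjusted over the list alone. Their median was 1.54 (camera adjusted p = 6.73e-05; adjusted p = 0.371 with an estimated correlation). Pericentral markers had 3 of 13 higher, 1 lower and 9 not passing, with 7 higher and 1 lower when adjusted over the list alone. Their median was 0.75 (camera adjusted p = 1.2e-05; adjusted p = 0.371 with an estimated correlation). Glul was 346 ± 8.81 with the diet against 57.6 ± 20.8 FPKM with CCl4 (2.61 ± 0.27, limma adjusted p = 0.0163). Of the 14 periportal markers 0 passed and 10 fell when adjusted over the list alone. Their median was -0.96 (camera adjusted p = 1.23e-08; adjusted p = 0.241 with an estimated correlation). Lower with the diet were Gstm3 at -3.16 ± 0.36, Gsta2 at -3.15 ± 0.34 and Cyp3a11 at -2.44 ± 0.28 (limma adjusted p = 0.0176, 0.0163 and 0.0176). Further lists passed camera at the preset correlation alone. Lipogenesis (median 0.72, camera adjusted p = 1.66e-08), acute phase genes (0.74, 2.14e-08), neutrophil markers (0.81, 9.55e-07) and immediate early genes (0.76, 8.72e-05) were higher, and NRF2 and glutathione genes lower (-0.63, 6.97e-06). Calls that ended without normal diet + CCl4 library 2 were cholesterol genes (-0.41, 0.000398; 0.869 without it), P450 genes (-0.65, 0.00167; 0.567), hepatocyte identity genes (-0.19, 0.00993; 0.805) and chemokine genes (0.52, 4.46e-05; 0.0987). The P450 call also ended without western diet + oil library 1 (0.0596). Calls that ended without CCl4 library 1 were the cell cycle (-0.9, 2.28e-05; 0.78) and male-biased genes (0.53, 0.00329; 0.412). Monocyte-derived macrophage markers (0.54, 0.0475) ended without normal diet + oil library 3 (0.0557), western diet + oil library 2 (0.208), normal diet + CCl4 library 2 (0.0928) and with median-of-ratios scaling (0.0768). The share of higher calls was 66.2%, and 55.6% (35 higher and 28 lower) without the Mup family. It turned to 37.5% (30 higher and 50 lower) without normal diet + CCl4 library 2, and was 100% of 6 with no filter. The count was 18 and 122 without normal diet + oil libraries 2 and 3, and 2 and 1 without western diet + oil libraries 1 and 2. Cidea passed limma without each library in turn, and Cfd in 6 of 8 such fits, being below the filter in the others.

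The interaction tested whether CCl4 acted differently under the western diet than under the normal diet. It passed for 7 genes, 4 positive and 3 negative, and rested on the single western diet + CCl4 library. Mup12 went from 12000 ± 6280 to 182 ± 12.4 FPKM with CCl4 under the normal diet but lay higher with CCl4 than with oil under the western diet, an interaction of 7.71 ± 0.72 on the log2 scale (SE; limma adjusted p = 0.0286). Mup13 at 5.81 ± 0.67, Mup15 at 4.80 ± 0.48 and Camp at 3.82 ± 0.39 were also positive (limma adjusted p = 0.0434, 0.0286 and 0.0286). Cfd at -4.17 ± 0.47, Cidea at -3.82 ± 0.37 and Slc16a5, a monocarboxylate transporter, at -2.97 ± 0.34 were negative (limma adjusted p = 0.0434, 0.0286 and 0.0434). Of the lists, 15 passed camera, led by the neutrophil markers, with 1 of 7 higher, 6 not passing and 7 higher when adjusted over the list alone. Their median was 3.60 (camera adjusted p = 1.51e-28; adjusted p = 0.0969 with an estimated correlation). With median-of-ratios scaling limma called 0 genes in the interaction, with 736 at an unadjusted p below 0.05 against 1126 in the deposited values. The count of 7 was 3 without normal diet + oil library 1 or 2, 1 without either western diet + oil library, and 0 and 168 without normal diet + CCl4 libraries 1 and 2, and none of the 7 genes passed in all of these fits. The split was 20 positive and 148 negative (11.9% positive) without normal diet + CCl4 library 2, 17 and 0 with no filter, and 131 and 502 with unadjusted p and 2-fold.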

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

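Each result given here passed the interaction term of limma or camera, which tests whether the effect of CCl4 differed between the 2 diets. The western diet + CCl4 group is 1 library, so this test does not separate an interaction from a property of that library. With median-of-ratios scaling limma called 0 genes in the interaction (736 at an unadjusted p below 0.05), and with an estimated correlation camera called 0 lists. Of the tests below, the one on the hepatocyte share with the western diet, the one on a wrong label and the one on depth with random gene sets were written after the results were seen, as were the fits without the Mup family and 1 library, the other tests were written before they were run, and both patterns were picked after the results were seen.

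Mup12 had an interaction of 7.71 on the log2 scale, Mup13 of 5.81 and Mup15 of 4.80, and these copies share fragments, so they are not separate findings. Camp had 3.82, Slc16a5 -2.97, Cidea -3.82 and Cfd -4.17. Each of the 7 values rests on the single western diet + CCl4 library. The median interaction of all 11514 tested genes was -0.293, and 0.00234 with median-of-ratios scaling. Part of each negative list median below may thus be an offset shared by all genes.

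Among the lists, the median interaction of the neutrophil markers was 3.60 (camera adjusted p = 1.51e-28; adjusted p = 0.0969 with an estimated correlation) and that of the male-biased genes 1.46 (2.44e-23; adjusted p = 0.0969 with an estimated correlation). The acute phase list had a median of 0.99 (4.07e-20; adjusted p = 0.183 with an estimated correlation), the cholesterol list 0.69 (3.22e-21; adjusted p = 0.276 with an estimated correlation) and the erythroid list 0.26 (0.0208; adjusted p = 0.728 with an estimated correlation). The xenobiotic P450 list had -0.61 (0.0101; adjusted p = 0.728 with an estimated correlation), fatty acid oxidation -0.69 (0.000488; adjusted p = 0.728 with an estimated correlation) and lipid droplets -0.86 (0.00472; adjusted p = 0.728 with an estimated correlation). Immediate early genes had -1.10 (0.0272; adjusted p = 0.758 with an estimated correlation), NRF2 and glutathione -1.17 (1.76e-05; adjusted p = 0.728 with an estimated correlation) and the extracellular matrix -1.19 (0.00772; adjusted p = 0.777 with an estimated correlation). Stellate cell markers had -1.35 (9.99e-05; adjusted p = 0.728 with an estimated correlation), sinusoidal endothelial markers -1.36 (4.99e-10; adjusted p = 0.535 with an estimated correlation), the cell cycle -1.43 (0.0023; adjusted p = 0.777 with an estimated correlation) and Kupffer cell markers -1.66 (9.99e-05; adjusted p = 0.728 with an estimated correlation). The matrix call ended without normal diet + oil library 1 (0.0746), western diet + oil library 2 (0.101) or normal diet + CCl4 library 1 (0.0809), and that of P450 without western diet + oil library 2 (0.101) or normal diet + CCl4 library 2 (0.741). The erythroid call ended with median-of-ratios scaling (0.0503) and without normal diet + oil library 3 (0.124), western diet + oil library 2 (0.472) or normal diet + CCl4 library 1 (0.194), and that of immediate early genes without normal diet + oil library 3 (0.123), western diet + oil library 2 (0.299) or normal diet + CCl4 library 2 (0.118).

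More genes were higher than lower against normal diet + oil, and the Mup share fell in the same libraries. If the Mup share were the whole cause, removing the family and making the sums equal was to bring the median log2 fold change of the tested genes under 0.1 and the share of higher calls to at most 60%. For the western diet the median went from 0.216 to 0.0983 and the share from 86.4% to 79.0%. Rescaling to a common sum with the family kept, which lets more genes through the filter, gave 0.324 and 90.7%. With normal diet + oil library 1 left out as well, 24 of 43 calls were higher (55.8%, median 0.0656), as the Mup share predicts, while the other 7 libraries left 61.5% to 100% higher. For CCl4 the median went from 0.264 to 0.147 and the share from 72.0% to 65.0%, against 0.453 and 84.3% when rescaled with the family kept. Without the family, the median and the share both fell under the limits when normal diet + oil library 1 was left out (46.7%, median 0.0987). Without normal diet + CCl4 library 1, which leaves 1 library in that group, the median was 0.046. The share was under its limit there too, so 2 of the 8 fits met both limits. The share ran from 41.7% to 87.7% over the 8 fits. In both comparisons the outcome turns with 1 library, so the Mup share and an effect of the treatment cannot be told apart. A lower share of hepatocytes with the western diet, and no other change, was to raise markers of all other cell types alike. The medians of Kupffer, stellate and endothelial markers (2.36, 0.94 and 0.89) spanned 1.47, more than the largest SD over members of 0.75. This gap cannot exclude a lower hepatocyte share together with more Kupffer cells. All 15 Kupffer, 16 stellate and 14 endothelial markers had a log2 fold change above 0. An effect of the western diet on transcription stays open beside the Mup share and a lower hepatocyte share.

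The 2 normal diet + CCl4 libraries stood apart: library 1 was above library 2 in all 20 cell cycle genes (median difference 1.93), all 24 matrix genes (1.29) and all 10 oncofetal genes (2.08). If library 2 were an oil library under a wrong label, at most 6 pericentral markers were to lie below the oil libraries. In library 2, 8 of 13 pericentral markers lay below all 3 normal diet + oil libraries, against 6 in library 1. The limit was set after the values were seen and library 1 falls under it too, so this count cannot exclude a wrong label. A difference in depth acts on genes by their level, so each list was to move like 1000 random gene sets of the same size and levels. Of all 29 lists tested with camera, written before the data were examined, 13 lay above and 5 below every such set, 18 in all, against 7 to 12 in other pairs of replicates. At most 2 lists were to lie outside, a limit that each of the other pairs broke too, so breaking it is not particular to this pair. The highest of the random sets reached 0.49 for the cell cycle, 0.52 for the matrix and 0.75 for the oncofetal list, below the medians of these lists. The sets drew genes singly and left out the correlation within a list (estimated at 0.91, 0.844 and 0.845). A shift by level alone did not reach these medians, but depth is unknown and is not excluded. Whether depth widened the spread over all genes cannot be told apart, with 4.73% of genes at 10 FPKM or more in both libraries differing by over 2-fold, against 1.10% to 4.97% in other pairs. A lower hepatocyte share in library 1 is open, with a gap of 0.54 between the 3 cell type medians against an SD over members of 0.78. No biological explanation was tested.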

How the results depend on the processing

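The alternatives without the Mup family, alone and with 1 library left out, and without both doubted libraries (normal diet + oil library 3 and normal diet + CCl4 library 1) were chosen after seeing the data. No alternative turned the direction of a named gene that passed, and robust eBayes left every count within 1.5 times. Of the 117 list calls, 111 held with median-of-ratios scaling and 117 without the Mup family, but 0 with an estimated correlation and 4 with fry. Named genes had 155 calls, and 49 with no filter and 65 with the replicate block. Of the 155, 111 held with median-of-ratios scaling and 110 with a pseudocount of 0.1. Depth is unknown, so its limits could not be set. Except where fewer genes or libraries entered by construction, the cause was not tested.

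Below, counts of genes are given in the order of the comparisons: western diet against normal diet, CCl4 against oil, western diet + CCl4 against normal diet + oil, against western diet + oil and against normal diet + CCl4, western diet + oil against normal diet + CCl4, and the interaction (508, 164, 107, 5, 30, 71 and 7 as reported). With no filter they were 121, 18, 171, 69, 109, 6 and 17. With both doubted libraries left out they were 780, 43, 315, 20, 60, 142 and 0. With unadjusted p and 2-fold they were 810, 588, 815, 195, 346, 410 and 633. With a pseudocount of 0.1 the 3 comparisons of western diet + CCl4 fell to 43, 0 and 15 and the interaction to 3. With a mean FPKM of at least 5, which tests fewer genes, the first became 190, the third 42, the fourth 0 and the interaction 3. Rescaling to a common sum, which lets more genes through the filter, gave 774 and 357 in the first 2. Median-of-ratios scaling gave 285 and 100 there and 0 in the interaction, and removal of the Mup family 315, 100 and 2. The fit of only the compared groups gave 1104 and 98, and the additive model 165 and 8. In fits of all libraries where limma called 0 genes, the counts at unadjusted p below 0.05 were 416, 223 and 436 in the fourth comparison (pseudocount, mean FPKM and block). In the interaction this count was 736 (median-of-ratios).

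No shared shift by replicate number was seen: differences between replicates 1 and 2 correlated at -0.209, -0.0768 and -0.0604 across groups. With so few pairs of libraries this cannot exclude a pairing or a batch. With the replicate number as a block, which leaves 2 residual degrees of freedom, the counts were 32, 49, 6, 0, 11, 55 and 2.

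Leaving out 1 library at a time moved the counts from 4 to 1159, 22 to 1165, 36 to 486, 1 to 16, 6 to 32, 1 to 122 and 0 to 168. With the Mup family removed as well, the first 2 ran from 3 to 841 and from 15 to 823. List calls ran from 106 (111 as reported over the same tests) to 129, apart from 51 of 51 without the western diet + CCl4 library, where fewer tests could be run. Without western diet + oil library 2 the neutrophil list had too few members above the filter for a test. Named genes ran from 26 (140 over the same tests) to 226 (154). The effect of leaving out the western diet + CCl4 library on comparisons that need it could not be computed. Where a list passed with all libraries or in the fit without 1 library, its direction turned in 12 cases. Turns between fits that both missed the threshold were not counted. Each case is given with the camera adjusted p where it turned and the range over all fits without 1 library. Without normal diet + CCl4 library 2, the matrix list turned to lower in western diet + CCl4 against normal diet + CCl4 (8.04e-05, range 1.35e-05 to 0.718) and in western diet + oil against normal diet + CCl4 (0.000596, range 3.94e-06 to 0.816). In these comparisons the cholesterol list turned to higher (0.0301, range 3.03e-07 to 0.109; 0.869, the highest, from 3.17e-10). In the second of them P450 genes turned to higher (0.567, the highest, from 3.25e-07) and monocyte-derived macrophage markers to lower (0.0928, range 2.05e-08 to 0.208). In the interaction these macrophage markers turned to lower (0.00112, the lowest, up to 0.863), and lipogenesis (0.0488, range 0.00466 to 0.977) and P450 genes (0.741, the highest, from 5.57e-07) to higher. Without library 1, the cell cycle turned to higher in western diet + CCl4 (0.479, the highest, from 6.89e-26) and in western diet + oil (0.78, the highest, from 2.34e-24) against normal diet + CCl4, and oncofetal genes in the latter (1.76e-05, range 4.29e-06 to 0.881). Other list calls were lost in 46 fits.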

Other observations

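Of the 2 tests on the clock genes below, that of a loss of transcripts was written after the results were seen and that of the time of day before it was run.

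Further lists moved with the western diet under oil. Of 7 neutrophil markers 1 rose, 6 did not pass and 6 rose when adjusted over the list alone. Their median was 0.81 (camera adjusted p = 0.00164; adjusted p = 0.503 with an estimated correlation), with S100a9 at 3.19 ± 1.99 and 17.7 ± 7.48 FPKM (2.21 ± 0.41, limma adjusted p = 0.0297). Of 24 interferon response genes 2 rose, 22 did not pass and 4 rose when adjusted over the list alone. Their median was 0.65 (camera adjusted p = 0.0111; adjusted p = 0.632 with an estimated correlation), with the antiviral enzyme Oas2 at 0.4 ± 0.0508 and 2.00 ± 0.0723 FPKM (limma adjusted p = 0.036). That call ended without normal diet + oil library 1 (0.0762). Of 12 immediate early genes 1 rose, 11 did not pass and 5 rose when adjusted over the list alone. Their median was 1.02 (camera adjusted p = 0.00662; adjusted p = 0.583 with an estimated correlation), a call that ended without western diet + oil library 2 (0.102), and the gene was the transcription factor Klf6 at 0.879 ± 0.121 and 4.94 ± 0.161 FPKM (limma adjusted p = 0.0216). Of 13 p53 targets 1 rose, 12 did not pass and 2 rose when adjusted over the list alone. Their median was 0.70 (camera adjusted p = 0.0313; adjusted p = 0.543 with an estimated correlation), a call that ended without western diet + oil library 1 (0.0592). That gene was Btg2, an antiproliferative factor, at 2.71 ± 0.44 (limma adjusted p = 0.0246), while Cdkn1a, the cell cycle inhibitor p21, did not pass (1.76 ± 0.55, limma adjusted p = 0.109). Periportal markers had 1 of 14 lower, 13 not passing, and 1 higher and 4 lower when adjusted over the list alone. Their median was -0.20 (camera adjusted p = 6.05e-05; adjusted p = 0.262 with an estimated correlation), with histidine ammonia-lyase (Hal) at 37.4 ± 6.87 and 12.8 ± 3.64 FPKM (limma adjusted p = 0.0466). Hepatocyte identity genes lay lower than other genes with 0 of 26 passing (median -0.09, camera adjusted p = 0.000141; adjusted p = 0.462 with an estimated correlation).

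Lists too short for a test gave values only. Ccl5, named after its values were seen, was the 1 of 3 T and NK cell markers that rose with the western diet, from 0.834 ± 0.219 (SD, n = 3) to 6.45 ± 3.15 FPKM (n = 2; 1.96 ± 0.26, limma adjusted p = 0.0152), and it also rose with CCl4, to 9.74 ± 0.138 (n = 2; 2.56 ± 0.26, limma adjusted p = 0.0053). The 4 tested B and plasma cell markers and the 4 cholangiocyte markers had 0 genes passing limma with the western diet or CCl4. The 1 tested skeletal muscle marker, Mylpf, did not pass with the western diet (0.37 ± 0.23, limma adjusted p = 0.375). The 1 tested exocrine pancreas marker, Cela1, went from 45.1 ± 8.36 to 15.1 ± 1.63 FPKM with the western diet (-1.51 ± 0.23, limma adjusted p = 0.0201). Both were named after their values were seen.

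Several clock genes had their lowest value in normal diet + oil library 3. Dbp was 0.481 FPKM there and 19.3 to 91.0 elsewhere, and Arntl, which peaks in the opposite phase, was 4.31 against 0 to 1.20. Of 16 clock genes 9 were lowest in this library and at most 1 in any other. The highest value was here in 4, in normal diet + CCl4 libraries 1 and 2 in 4 and 7, and in western diet + oil library 2 in 1. A general loss of transcripts in library 3 was to leave 0 highest there, against the 4 seen. FPKM is a share of each library, so such a loss could cancel out, and this count does not decide it. Collection at another time of day is a hypothesis: of 3 clock-controlled genes outside the list, 2 were lowest in this library (Usp2 at 0.467 and Wee1 at 0 FPKM), while Lonrf3 was at 0 in most libraries and decided nothing, so this cannot be told apart from other causes. No biological explanation was tested, and the times of collection are not given in the sources used here.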
